A study of Homo sapiens with 8 samples.

How the data were processed

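Gene expression was measured in HepG2 cells, a line derived from a human hepatocellular carcinoma, after 48 h in glucose-free medium to which glucose had been added at a low (40 mg/dL) or a high (450 mg/dL) concentration. Each group had 4 samples, and each sample was labelled with Cy3 and hybridised to its own array. The group and replicate number of each array came from its source label. In a free-text label, the high glucose samples carry the concentration of the low glucose medium, whereas the treatment protocol and the series design state 450 mg/dL, which was used here. The labels do not say whether the 4 replicates of a group were separate cultures, so all p-values measure the spread between these samples, which may be technical.

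Per the file headers, the arrays were 1-colour Agilent arrays of design 026652, scanned in 2 passes and read with Feature Extraction 12.0.3.1 on a grid of genome build hg19 (Agilent Feature Extraction version 12 per the submitters' processing notes). The deposited processed intensity of each spot had been corrected for background and spatial trend within its array, per the file headers, and had not been normalised between arrays. The deposited table of the whole series held the same processed intensities on a linear scale, neither centred nor rescaled: each value equalled that of the spot with the same feature number in the scanner file of its sample. Each array had 44495 spots, of which 1377 were control spots and were left out. The remaining 43118 spots carried 34127 probes, 33128 of them spotted once and 999 spotted 10 times.

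Values were taken from the processed intensity, set to missing where Feature Extraction had marked a spot as an outlier, converted to log2 and expressed relative to the 75th percentile of their array. Spots of one probe were averaged. A probe counted as measured on an array where at least a share of 0.5 of its spots lay well above background, and it was tested where it was measured on all 4 arrays of at least 1 group. The files name probes by accession. Accessions were matched without version to a RefSeq gene table of assembly GRCh38.p14, which named 26992 probes (79.1%), and the other probes stood for themselves. Since this assembly differs from the build of the arrays' grid, no coordinates are given. The probe with the highest mean signal stood for its gene. This left 15984 features, 13491 with a gene symbol and 2493 without. A further 2960 tested probes belonged to genes whose brightest probe passed the threshold, and 2522 of them (85.2%) differed in the same direction as the brightest probe, while 243 passed the threshold in the opposite direction.

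High and low glucose were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with no covariate, and p-values were adjusted by the Benjamini-Hochberg method over all features, with a threshold of 0.05. Differences are high minus low glucose. A gene not well above background on any array of a group has only a bound there. For such a gene, the mean of the brighter group was set against the mean, over the arrays of the dimmer group, of the higher of the probe's own value and the lowest value among probes well above background, and the result is given as the fold at its bound. Since the lowest such value was used, this fold is not a strict minimum. Of the features tested, 373 were not well above background on any low glucose array and 121 on any high glucose array.

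37 gene lists (pathways, liver functions, stress responses and markers of other cell types) were fixed before the data were examined, as were the design, the alternatives and the rule for naming genes. Lists with at least 5 tested genes were compared with the other genes by camera, with a preset inter-gene correlation of 0.01, and camera with a correlation estimated for each list and fry, which asks whether the genes of a list move one way on balance, were run beside it. Features with a missing value (6) did not enter these tests. The rule named the 10 largest increases and the 10 largest decreases among genes with a symbol, an adjusted p under 0.05, no overlap between the groups and a signal well above background on all 8 arrays. It also named up to 4 members with the smallest adjusted p of each list past the threshold, and 18 check genes whatever their result, which gave 92 genes, 4 of which are not reported here. Their 14 other tested probes all differed in the direction of the brightest probe. 7 further lists were chosen after the largest changes had been seen and are used in the closing section only.

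The procedure was tested on simulated data for this comparison, with the means and spreads of 15978 features and 200 of them changed. It recovered 6% of the features changed by a log2 difference of 0.25, 64% of those changed by 0.5, 86% of those changed by 1 and 98% of those changed by 2, with 3 false calls among 130. These rates hold for few changed features with independent noise. In the data 11511 features passed, which makes the adjusted threshold less strict, so the rates do not carry over to the comparison itself. The number of arrays, 4 in each group, limits the precision.

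The array identifiers placed the 8 arrays on 4 slides, each holding 1 low and 1 high glucose array, so that slide and group could be separated. The low glucose array was at the same position on every slide and the high glucose array at another, so that position on the slide coincided with group. Alternatives were normexp background correction with an offset of 50, quantile and median scaling, no filter and a stricter filter on dim probes, every probe tested, outlier spots kept, replicate number as a block, slide as a fixed or a random block (with camera applied to the moderated statistics), an intensity trend with robust variances, array weights, the series table, and leaving out each array. The normexp correction was planned on mean signals, and was run on the median spot and background signals, since the files used here have no column of mean signals. Scaling to the labelled spike-in controls was added after the data were seen, as was the comparison of single folds with those under normexp. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.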

Results

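Transcript levels were measured on 8 one-colour arrays of HepG2 cells, a human hepatocellular carcinoma line, to find which genes respond to the glucose concentration of the medium. 4 samples had been kept for 48 h in medium with 40 mg/dL glucose and 4 in medium with 450 mg/dL. On the low glucose arrays, 26282 ± 471 spots (SD, n = 4) of 43118 lay well above background, and on the high glucose arrays 27156 ± 446 did (exact permutation test, two-sided p = 0.0571, where 0.0286 is the smallest the design allows). The high glucose arrays were also brighter on average, with a 75th percentile of the processed signal of 403 ± 35.5 against 330 ± 43.8 (SD, n = 4; exact permutation p = 0.0571), and neither difference passed the test. No spot was saturated. Values below are log2 signals relative to the 75th percentile of the array.

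The 2 groups of arrays were clearly separated. Over the features tested, the mean Pearson correlation between arrays of one group was 0.995, and that between arrays of different groups was 0.932. This difference of 0.0636 was the largest of the 35 possible splits of the arrays into 4 and 4 (exact permutation share 0.0286, the smallest the design allows). The first principal component held 89.9% of the variance and parted the groups. Probes spotted 10 times had a median SD of 0.066 over the single spots of one array, and the median SD of their 10-spot means over the arrays of one group was 0.0654.

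Most of the transcripts measured differed between high and low glucose. The largest increase met by the naming rule was that of ERP27 (probe A_23_P139687), a non-catalytic relative of the protein disulfide isomerases, which was 129-fold higher in high glucose (log2 difference 7.01 ± 0.09, SE). It was followed by TXNIP, the thioredoxin-interacting protein and a known glucose-responsive gene, which was 83.5-fold higher (3.96 ± 0.03 in high and -2.42 ± 0.13 in low glucose, SD, n = 4; limma adjusted p = 2.26e-10). The other large increases were haptoglobin (HP, 81.9-fold), the haptoglobin-related gene HPR (80.2-fold), the thyroxine-binding globulin SERPINA7 (64.7-fold), the sphingolipid synthesis gene SPTLC3 (57.1-fold), the plasma carboxypeptidase CPB2 (51.1-fold), TMEM121 (38.7-fold), apolipoprotein APOC3 (37.6-fold) and ASB9 (32.3-fold). HP and HPR are close paralogs, and their probes may not separate them. The largest decrease was that of AQP3, a water and glycerol channel (probe A_23_P112482), which was 198-fold higher in low glucose (2.26 ± 0.11 against -5.37 ± 0.17, SD, n = 4; limma adjusted p = 3.66e-10). The lysosomal membrane protein gene LAMP3 was 96.1-fold higher in low glucose, RGCC 89.8-fold, the osteoclast-associated receptor OSCAR 59.8-fold, the progestin receptor PAQR5 57-fold, the transporter SLC22A15 48.3-fold, the Notch target HEY1 48.2-fold, C11orf96 47.5-fold and KLHDC7B 47.1-fold. All these genes differed beyond the replicate spread, with limma adjusted p-values of at most 2.91e-08. Their sizes depended on the background correction. Under normexp correction, which adds an offset of 50 to every signal, 18 of these 19 folds were smaller by over 1.5 times, with ERP27 at 23.8-fold, TXNIP at 43.7-fold, CPB2 at 8.16-fold, AQP3 at 28.7-fold and LAMP3 at 15.2-fold, and all 18 passed the test in the same direction. Their order changed too. Of these genes, HP then had the largest increase (45.4-fold higher in high glucose) and RGCC the largest decrease (41.8-fold higher in low glucose).

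**Figure D1:**
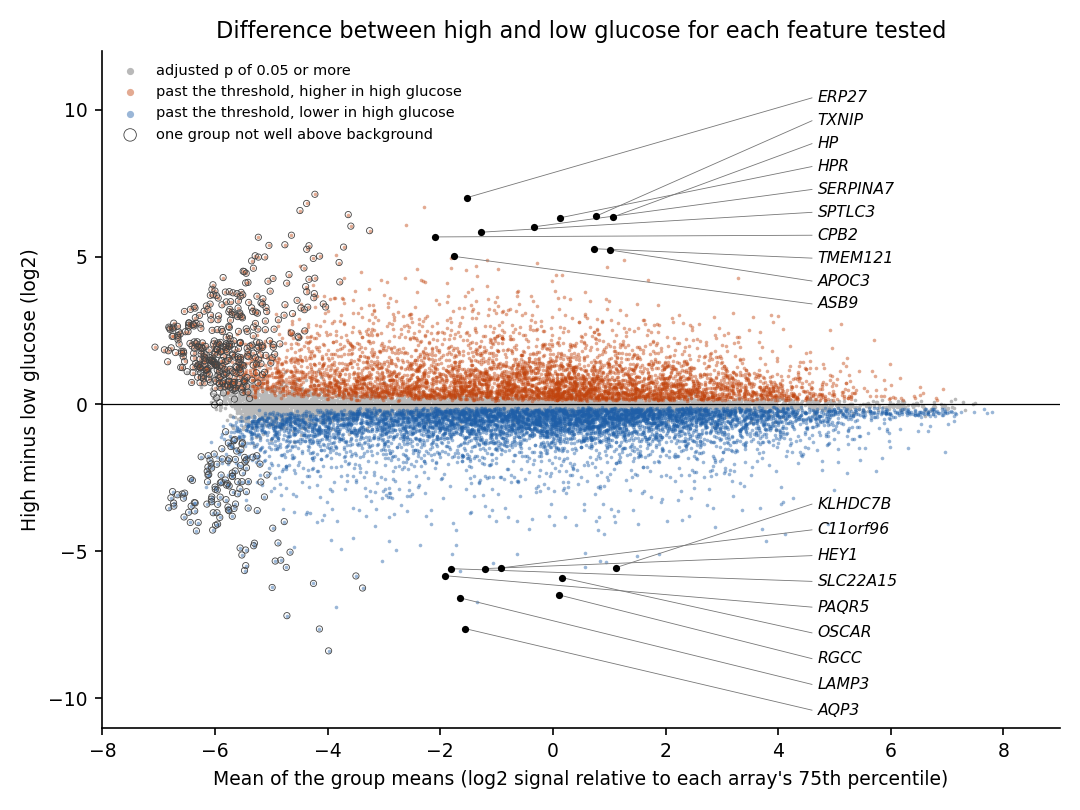
Log2 difference between high and low glucose (vertical axis, high minus low) against the mean of the group means (horizontal axis, log2 signal relative to each array's 75th percentile) for the 15984 features tested, with the largest increases and decreases named in the text labelled. Coloured points passed the threshold, 5246 above and 6265 below 0, grey points did not, and open circles mark features not well above background on any array of one group, whose difference is not a measured size.

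Of 15984 features, 11511 (72%) passed an adjusted p of 0.05 in limma, 5246 of them higher and 6265 lower in high glucose. The differences were often small, with 4085 of these features under 0.5 on the log2 scale. With features that lacked a signal in one group set to their bound, 1849 were higher and 1644 lower by a log2 difference of at least 1 (1993 and 1645 at the fitted values). Under normexp correction the counts at the fitted values were 956 and 851. The folds of 39 of 88 named genes were then smaller by over 1.5 times, and 38 of these 39 genes passed the test in the same direction. With no filter on dim probes, 27643 features were tested, of which 5184 were higher and 9590 lower. For 10786 features (67.5%) the groups did not overlap, against 2.86% by chance. With slide as a fixed block 11121 features passed. The position of an array on its slide coincided with its group.

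Targets of ChREBP, the transcription factor that responds to glucose metabolites in liver cells, and genes of fatty acid synthesis were higher in high glucose. Of 23 members tested, 21 rose, none fell and 2 did not pass the test (21 rose and 1 fell adjusted over the list alone), with a median log2 difference of 0.96 (camera adjusted p = 9.43e-08; adjusted p = 0.116 with an estimated correlation). Besides TXNIP, the liver pyruvate kinase PKLR rose 17.8-fold, the arrestin-related ARRDC4 8.96-fold and the triokinase TKFC 7.71-fold. MLXIPL, which encodes ChREBP, rose 2.63-fold, fatty acid synthase (FASN) 1.95-fold (0.96 ± 0.06 log2, SE) and the stearoyl-CoA desaturase SCD 1.39-fold. G6PC1, the catalytic subunit of glucose-6-phosphatase, was not well above background on any low glucose array. It was 18.3-fold higher in high glucose at its bound (limma adjusted p = 4.5e-06), but 2.54-fold under normexp correction, where PKLR was 3.71-fold and ARRDC4 4.13-fold higher. PCK1, the cytosolic enzyme of gluconeogenesis, was 1.54-fold higher (adjusted p = 0.00573), but 0.02 higher on the log2 scale under normexp correction (limma adjusted p = 0.84). Hexokinase HK2 rose 1.22-fold (limma adjusted p = 0.00137; 0.0667 when scaled to spike-in controls). The glucose transporter SLC2A1 had a log2 difference of -0.43 ± 0.31 (SE, adjusted p = 0.233), and high glucose replicate 4 lay far below the other 3. Without that array the difference was -0.08 (limma adjusted p = 0.255). As lists, genes of gluconeogenesis (8 of 12 rose and 3 fell, median 0.51, camera adjusted p = 0.0641), the TCA cycle (12 of 24 rose and 4 fell, median 0.30, adjusted p = 0.0641) and the pentose phosphate pathway (5 of 10 rose and 4 fell, median 0.22, adjusted p = 0.913) did not pass. Nor did glycolysis, where 11 of 21 rose and 5 fell, or 6 adjusted over the list alone (median 0.28, or 0.22 with 1 member at its bound; adjusted p = 0.199). Gluconeogenesis passed without low glucose replicate 1 (adjusted p = 0.0417) and, like the TCA cycle, under normexp correction (adjusted p = 0.0357 and 0.0119) and with no filter on dim probes (adjusted p = 0.0113 and 0.00232), where glycolysis also passed (adjusted p = 0.0235). The median was 0.30 for gluconeogenesis over probes well above background on all 8 arrays, and 0.15 for glycolysis and -0.003 for the pentose phosphate pathway under normexp correction. With no filter it was 0.39 for gluconeogenesis, 0.20 for glycolysis and unchanged at 0.30 for the TCA cycle. The median of all features was then -0.30, against -0.08 with the filter. Camera compares a list with the other genes, so these calls do not mean larger shifts of the lists.

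Sterol genes went both ways. Of 24 genes of cholesterol synthesis and its regulation, 13 rose and 6 fell, with a median of 0.14, 0.27 under quantile scaling and 0.07 when scaled to spike-in controls (camera adjusted p = 0.1), and the list passed under quantile scaling (adjusted p = 0.0354), normexp correction (adjusted p = 0.0125) and with no filter (adjusted p = 0.0135). With no filter its median was 0.13, while that of all features was lower than with the filter.

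Genes for proteins that hepatocytes secrete were higher in high glucose. Of 37 tested, 28 rose, 1 fell and 8 did not pass (28 rose and 2 fell adjusted over the list alone), with a median log2 difference of 1.13, or 0.68 under normexp correction (camera adjusted p = 1.16e-07; adjusted p = 0.28 with an estimated correlation). Plasminogen (PLG) rose 20.5-fold and ITIH1, an inter-alpha-trypsin inhibitor chain, 12.8-fold, in addition to HP and APOC3. Under normexp correction PLG was 7.09-fold and ITIH1 7.43-fold higher. Albumin (ALB) had a log2 difference of -0.20 ± 0.08 (SE, limma adjusted p = 0.0526), which passed the test under 5 of 22 alternatives. Its adjusted p ran from 0.0143, without low glucose replicate 4 (log2 difference -0.26), to 0.741. Among acute phase genes 12 of 13 rose and 1 fell (median 1.80, camera adjusted p = 1.45e-05; adjusted p = 0.0534 with an estimated correlation). SAA4 rose 9.3-fold and the complement protease C1S 3.89-fold (2.31-fold under normexp correction), and the exception was hepcidin (HAMP), the iron-regulatory hormone, which was 10.5-fold higher in low glucose. Of 22 hepatocyte transcription factors 16 rose and 4 fell (median 0.52, camera adjusted p = 0.013; adjusted p = 0.243 with an estimated correlation). The nuclear receptors NR1I2 and RXRA rose 3.41-fold (1.88-fold under normexp correction) and 2.71-fold and the pioneer factor FOXA1 1.73-fold, while CEBPB was 2.86-fold higher in low glucose. In bile acid synthesis and transport 10 of 13 genes rose and 3 fell (median 1.05, or 0.36 with no filter on dim probes; camera adjusted p = 0.0234; adjusted p = 0.226 with an estimated correlation, and 0.174 for probes well above background on all 8 arrays). CYP8B1, the sterol 12-alpha-hydroxylase, was not well above background on any low glucose array. It was 29.3-fold higher in high glucose at its bound, but 3.59-fold under normexp correction. The 3 that fell were the transporter subunit SLC51B (6.19-fold higher in low glucose, or 4.13-fold under normexp correction), the phospholipid exporter ABCB4 (3.91-fold) and the bile acid conjugating enzyme BAAT (2.52-fold).

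Cell cycle genes were higher in high glucose almost without exception. All 30 tested genes of G2/M and mitosis rose, by a median log2 difference of 1.88 (camera adjusted p = 1.59e-14; adjusted p = 0.0862 with an estimated correlation), and 32 of 34 genes of DNA replication and G1/S rose and none fell, by a median of 1.87 (camera adjusted p = 1.81e-13). The second list was the only one of the 16 past the threshold that also passed with an estimated correlation (adjusted p = 0.0495). Among mitotic genes KIF20A rose 10.8-fold, topoisomerase TOP2A 7.26-fold, cyclin CCNA2 5.04-fold (2.33 ± 0.04 log2, SE) and survivin (BIRC5) 4.72-fold. Among replication genes E2F2 rose 14.2-fold, UHRF1 12.5-fold, the licensing factor CDT1 7.25-fold and GINS2 6.98-fold. The proliferation marker MKI67 was not well above background on any low glucose array. It was 8.64-fold higher in high glucose at its bound (limma adjusted p = 1.26e-07), but 1.52-fold under normexp correction. With that correction KIF20A was 2.72-fold, CCNA2 2.89-fold, TOP2A 4.67-fold, E2F2 7.79-fold and UHRF1 8.09-fold higher. The cell cycle inhibitor CDKN1A was 1.49-fold higher in low glucose (adjusted p = 0.000672). Replication-dependent histone genes went both ways, 5 of 13 up and 7 down (median -0.25, camera adjusted p = 0.913), as did p53 targets, 11 of 21 up and 8 down (median 0.39, or 0.05 under normexp correction; adjusted p = 0.19, and 0.021 with no filter on dim probes). With no filter the median of p53 targets was the same, 0.39, while that of all features was lower.

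**Figure D2:**
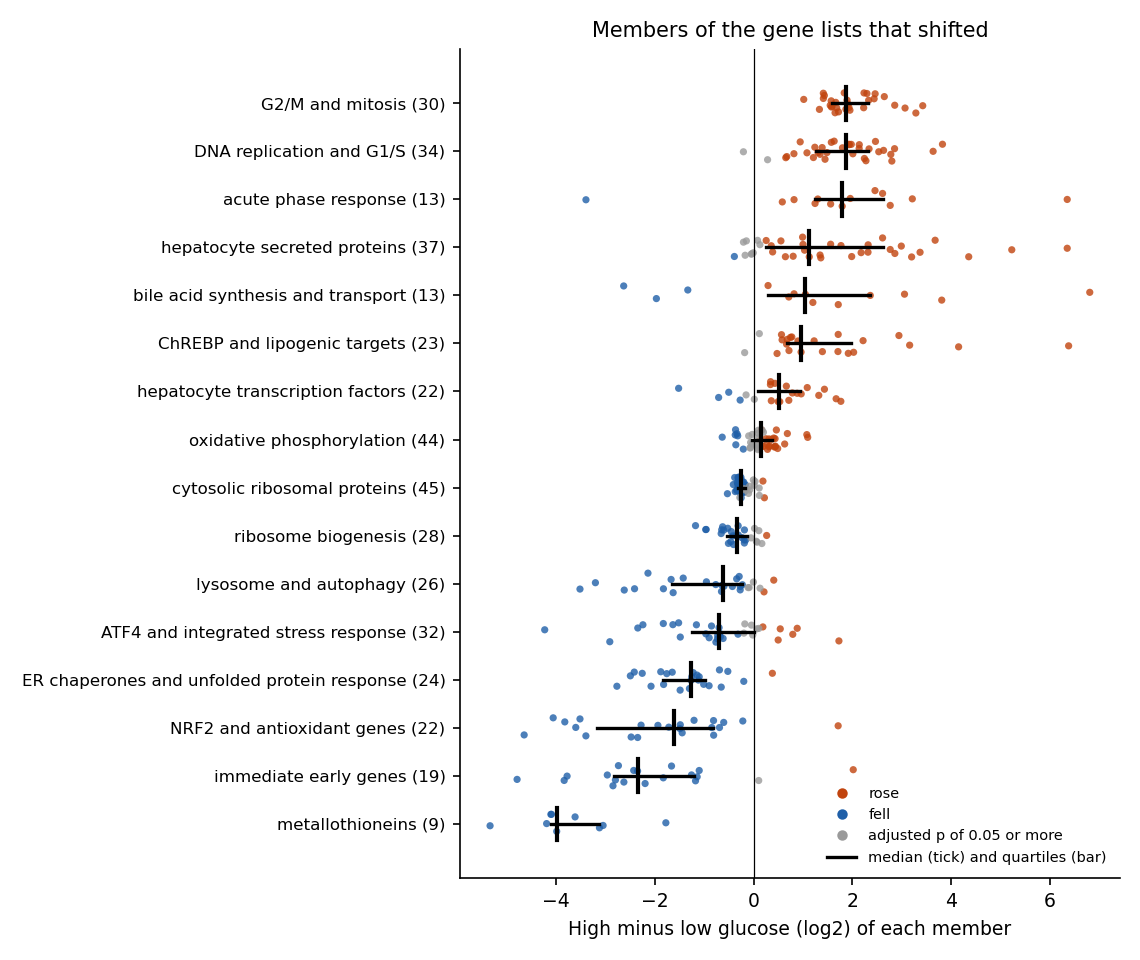
Log2 difference between high and low glucose (horizontal axis, high minus low) for every tested member of the 16 gene lists past the camera threshold, with the number of members tested in brackets, ticks at the median and bars from the lower to the upper quartile. Medians run from -3.99 for metallothioneins to 1.88 for G2/M and mitosis, and all members of those 2 lists lie on one side of 0, whereas the other lists have members on both sides.

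Oxidative and metal stress genes were lower in high glucose. Of 22 NRF2 targets and antioxidant genes, 21 fell and 1 rose (median -1.60, camera adjusted p = 1.47e-07; adjusted p = 0.0862 with an estimated correlation). The aldo-keto reductase AKR1B10 was 25.1-fold higher in low glucose, heme oxygenase HMOX1 16.7-fold (6.92 ± 0.07 against 2.86 ± 0.10, SD, n = 4), thioredoxin reductase TXNRD1 12.1-fold (4.6-fold under normexp correction) and sulfiredoxin SRXN1 10.5-fold. Metallothioneins bind zinc and copper, and all 9 tested members of their list fell (median -3.99, camera adjusted p = 4.26e-06, or 0.19 with an estimated correlation). MT2A was 18.3-fold, MT1L 17.2-fold, MT1X 17.1-fold (11.4-fold and 11.3-fold under normexp correction) and MT1B 15.9-fold higher in low glucose. Since the MT1 genes are near-identical, these are not independent measurements. Immediate early genes, which are induced rapidly by growth factors and stress, also fell, 17 of 19 with 1 rising (median -2.35, -2.20 with 1 member at its bound and -1.12 under normexp correction; camera adjusted p = 1.78e-05; adjusted p = 0.14 with an estimated correlation). The phosphatase DUSP5 was 27.7-fold (7.07-fold under normexp correction), EGR1 7.8-fold, the mRNA-destabilising ZFP36 7.2-fold and KLF6 5.38-fold higher in low glucose.

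Genes of protein folding in the endoplasmic reticulum were lower in high glucose. Of 24 tested, 23 fell and 1 rose (median -1.26, camera adjusted p = 1.73e-07; adjusted p = 0.189 with an estimated correlation). DNAJC3 was 5.64-fold, the chaperone BiP (HSPA5) 4.77-fold (log2 difference -2.26 ± 0.05, SE), DNAJB11 4.22-fold and DERL2 3.38-fold higher in low glucose. In the ATF4 and integrated stress response list 20 of 32 genes fell and 6 rose (21 and 7 adjusted over the list alone), with a median of -0.69 (camera adjusted p = 0.00977; adjusted p = 0.311 with an estimated correlation). PPP1R15A, a regulatory subunit of the eIF2-alpha phosphatase, was 18.8-fold (10.2-fold under normexp correction), CHOP (DDIT3) 7.53-fold and the tryptophanyl-tRNA synthetase WARS1 5.08-fold higher in low glucose, while asparagine synthetase (ASNS), another ATF4 target, had a log2 difference of -0.02 ± 0.04 (SE, limma adjusted p = 0.75; 0.17 with adjusted p = 0.00573 under quantile scaling). Heat shock genes did not pass as a list (3 of 16 rose and 8 fell, median -0.26, or -0.16 under quantile scaling; camera adjusted p = 0.188), nor did the hexosamine pathway (2 of 11 rose and 7 fell, median -0.80, adjusted p = 0.149).

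**Figure D3:**
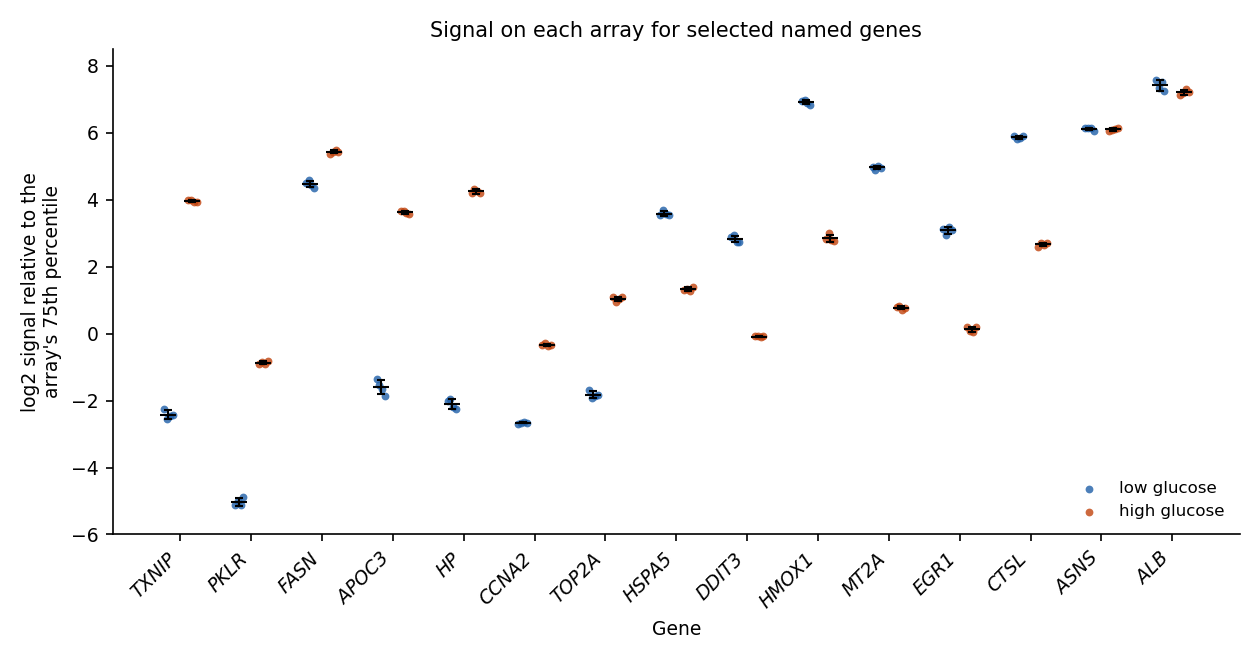
Log2 signal relative to the array's 75th percentile (vertical axis) on each of the 4 low and 4 high glucose arrays for 15 named genes (horizontal axis), with the mean and SD of each group in black; levels are to be compared within a gene, not between genes. The groups do not overlap for the 13 genes from TXNIP to CTSL, whereas ASNS (6.10 in high and 6.12 in low glucose) and ALB (7.22 and 7.42) differ by little.

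Lysosome and autophagy genes were lower in high glucose, with 20 of 26 falling and 2 rising (20 and 3 adjusted over the list alone), by a median of -0.62 (camera adjusted p = 0.000197; adjusted p = 0.143 with an estimated correlation). The autophagy receptor SQSTM1 was 11.4-fold, the cathepsins CTSL and CTSB 9.21-fold and 6.15-fold, and MAP1LC3B 4.4-fold higher in low glucose. Smaller shifts were seen in genes of protein synthesis and respiration. Of 28 ribosome biogenesis genes, 21 fell and 1 rose (median -0.33, camera adjusted p = 0.0128; adjusted p = 0.319 with an estimated correlation, and 0.0604 under normexp correction), among them MYC (2.26-fold higher in low glucose), RRP12 (1.95-fold), NOP16 (1.56-fold) and BYSL (1.52-fold). Of 45 cytosolic ribosomal protein genes, 32 fell and 2 rose (median -0.26, camera adjusted p = 0.0234; adjusted p = 0.705 with an estimated correlation), and the shift did not pass under quantile scaling (median -0.07, adjusted p = 0.706) or normexp correction (adjusted p = 0.154). RPL8 was 1.3-fold and RPL38 1.25-fold higher in low glucose. Of 44 oxidative phosphorylation genes, 22 rose and 7 fell (median 0.15, 0.28 under quantile scaling and 0.08 when scaled to spike-in controls; camera adjusted p = 0.0401; adjusted p = 0.357 with an estimated correlation), with ATP5F1D up 2.14-fold and NDUFA2 2.11-fold. That call was lost without high glucose replicate 3 (adjusted p = 0.0516) and with scaling to spike-in controls (adjusted p = 0.0883).

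Other lists did not pass the camera test. Interferon-stimulated genes came nearest, with 14 of 23 rising and 8 falling (median 0.93, or 0.61 with 2 members at their bound, camera adjusted p = 0.0552). They passed with slide as a fixed block (camera adjusted p = 0.0421), but not with slide as a random block. They also passed with scaling to spike-in controls (0.0201) and with no filter on dim probes (0.0232). They passed as well without low glucose replicate 2 (0.0441), low glucose replicate 4 (0.0426) or high glucose replicate 1 (0.0499). Their median was 0.11 under normexp correction (adjusted p = 0.0604), 0.26 with no filter and 0.61 over probes well above background on all 8 arrays (adjusted p = 0.0837). TGF-beta, YAP and matrix genes (4 of 21 up and 14 down, median -0.38, adjusted p = 0.0819), fatty acid oxidation and ketogenesis (13 of 23 up and 6 down, median 0.39, adjusted p = 0.0882; 0.0321 under normexp correction and 0.00827 with no filter), hypoxia genes (10 of 22 up and 6 down, median 0.15, adjusted p = 0.314), FOXO and insulin-repressed genes (8 of 13 up and 5 down, median 0.38, adjusted p = 0.266) and circadian clock genes (7 of 16 up and 8 down, median -0.27, adjusted p = 0.913) had members in both directions. Under normexp correction the median was 0.20 for fatty acid oxidation, 0.04 for hypoxia genes and 0.02 for FOXO genes, and with no filter it was 0.20, 0.07 and 0.18, and -0.45 for circadian clock genes. Inflammatory and NF-kB targets had 7 of 16 up and 6 down (7 down adjusted over the list alone; median -0.08, or 0.04 over probes well above background on all 8 arrays and -0.33 with no filter; adjusted p = 0.944). Xenobiotic metabolism had 9 of 19 up and 7 down (median 0.28, or -0.04 under normexp correction and -0.25 with no filter; adjusted p = 0.64). Among markers of other cell types, cholangiocyte and progenitor genes had 6 of 11 up and 2 down (median 1.10, or 0.56 with 2 members at their bound, -0.06 under normexp correction and 0.01 both with no filter and over probes well above background on all 8 arrays; adjusted p = 0.227) and macrophage and blood cell genes, of which 7 of 18 were measured, 3 up and 2 down (adjusted p = 0.608). Only 4 of 12 endothelial genes (1 up, 2 down) and 4 of 15 fibroblast and stellate cell genes (1 up, none down) were measured, too few to test. Median, mean and camera direction differed in sign for 3 lists, and fry gave a downward direction, against an upward median and mean, for the cholangiocyte and pentose phosphate lists. The macrophage list had a median of -0.11 (-0.20 under normexp correction and -0.34 with no filter) and a mean of 0.90 with an upward test direction, the xenobiotic list a median of 0.28 and a mean of -0.03 with an upward direction, and the inflammatory list a median of -0.08 and a mean of -0.32 with an upward direction.

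Each of the 16 lists past the threshold kept the sign of its median within all 4 slides and passed with slide as a fixed block, with camera adjusted p-values up to 0.0396. For the replication list the medians within slides ran from 1.76 to 1.92, for the ChREBP list from 0.92 to 1.15, for the endoplasmic reticulum list from -1.42 to -1.17 and for metallothioneins from -4.13 to -3.74. Of the 92 genes named by the rule, 89 passed the threshold, and all 89 also passed with slide as a fixed block. Apart from the check genes, the rule had picked them by their adjusted p on these same arrays, as the 16 lists had been. These counts are therefore no independent support. Of all 11511 features past the threshold, 10864 (94.4%) also passed with slide as a fixed block. Adjusted over the list alone, counts are given above only where they differ from those adjusted over all features.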

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

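The gap of the highest or lowest array to its nearest neighbour was set against the range of its group of 4 for 88 named genes and 3 array measures (182 groups). It passed the 95% critical value in 10 groups, where chance would give 9.1, so that the number of such groups is near that expected by chance. The spots well above background, the 75th percentile of the signal and the number of outlier spots gave none.

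SLC2A1 lay at 2.82 on the array of high glucose replicate 4, while the other 3 high glucose arrays lay between 4.16 and 4.25. On the same array RXRA was lowest at 1.5 (the next array 1.55). Low glucose replicate 4 was lowest for ASNS at 6.07 (next 6.13) and for CPB2 at -5.12 (next -4.88). High glucose replicate 2 was highest for MAP1LC3B at 2.51 (next 2.45) and lowest for PAQR5 at -5.02 (next -4.78). The other 4 were low glucose replicate 2 for HEY1, lowest at 1.24 (next 1.69), low glucose replicate 3 for UHRF1, highest at -1.46 (next -1.65), high glucose replicate 3 for DDIT3, lowest at -0.11 (next -0.08), and high glucose replicate 1 for UQCRQ, lowest at 5.27 (next 5.37).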

How the results depend on the processing

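Scaling to spike-in controls was chosen after the data were seen, and all other alternatives before. Of 150 alternative values of the counts, the number of lists and the similarity of arrays, 145 were labelled unchanged. Counts had to stay within 1.5 times of the value reported, while the similarity difference only had to stay above 0. That difference was 0.0222 with no filter on dim probes and 0.0506 under normexp correction, against 0.0636 reported. Normexp correction gave 956 features higher and 851 lower by a log2 difference of at least 1 (1993 and 1645 reported), with 36.3% of the features past the threshold higher in high glucose against 45.6%. With no filter on dim probes, where 27643 features were tested, 9590 were lower (6265 reported) and 35.1% of those past the threshold were higher. The cause of these changes was not tested, though an added offset of 50 by construction narrows the folds of dim probes. The folds of 39 of 88 named genes moved by over 1.5 times under normexp, all to smaller values. Camera with an estimated correlation called 1 list and fry, which compares no list with other genes, called 32 (16 reported). The median difference over all features was -0.08, and among the scalings it ran from -0.15 with spike-in controls to -0.03 with quantiles. With no filter on dim probes it was -0.30. Camera sets a list against the other genes. Upward calls gained with no filter, among them those of fatty acid oxidation and interferon-stimulated genes, were therefore made against lower genes. Leaving out 1 array at a time gave 10886 to 11504 features past the threshold, 4980 to 5204 higher and 5885 to 6362 lower, 1954 to 2030 higher and 1621 to 1698 lower by at least 1, 15 to 17 lists, and differences in correlation of 0.0604 to 0.0643. Scaling to spike-in controls gave 11121 features, of which 10720 were among the 11511 reported. Array weights gave 12196. The series table holds the same values as the scanner files and could change nothing. Nor could list tests with every probe tested, which used the same brightest probes. Median and spike-in scaling shift whole arrays, so they could not change the similarity of arrays. The counts of unchanged values here and below include these.

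Of 840 alternative values for single lists, 784 stayed on their side of the threshold, 21 fell below it (15 of these with an estimated correlation, 0.0534 to 0.705), 32 rose above it and 3 reversed. The reversals were all downward calls by fry of lists that camera had placed upward without calling them, namely the pentose phosphate pathway (adjusted p = 0.00815), xenobiotic metabolism (3.02e-05) and inflammatory and NF-kB targets (0.000146). Of 2021 values for named genes, 2012 stayed, 3 fell below the threshold, 5 (all for ALB) rose above it and 1 reversed. The reversal was ASNS at 0.17 under quantile scaling, against -0.02. The cause of these was not tested.

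Arrays with the same replicate number did not deviate together throughout (correlations of their deviations from the group means 0.07, 0.14, -0.01 and 0.03), so the numbers were not taken to pair samples. With the replicate block 11715 features passed, 11236 of them shared with the 11511 reported, and 17 lists, the added one being the TCA cycle (adjusted p = 0.0461). Not every array correlated best with its own number. Signal over background limits the results for dim genes, since 373 features had no signal well above background on any low glucose array and 121 on any high glucose array.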

Other observations

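The lists and genes in this part were chosen after the largest changes had been seen, the tests of scaling and of macrophage transcripts were chosen after their results were in part known, and the restriction of the spike-in test to 8 probes was chosen after the differences of all 10 had been seen. Complement and coagulation genes, which the liver makes for the blood, were higher in high glucose. Of 40 tested, 38 rose and 2 fell, with a median log2 difference of 2.01, 1.95 with 5 members at their bound and 1.17 under normexp correction (camera adjusted p = 5.8e-14 over the 7 lists; adjusted p = 0.0604 with an estimated correlation). 13 of the 40 also belong to lists of the report, and of the other 27, 26 rose and 1 fell. Complement factor CFI was 29.7-fold, C8A 15-fold and protein Z (PROZ) 13-fold higher in high glucose (21.3-fold, 6.37-fold and 2.8-fold under normexp correction), and the 2 that fell were antithrombin (SERPINC1, log2 difference -0.39 ± 0.04, SE) and the C1 inhibitor (SERPING1, -0.65 ± 0.18). Genes of amino acid breakdown and the urea cycle rose more often than they fell, 20 against 7 of 31 (median 0.43, or 0.27 under normexp correction; camera adjusted p = 0.00303; adjusted p = 0.1 with an estimated correlation), with AGXT up 17.3-fold (5.58-fold under normexp correction) and GLUD1 4.87-fold, while KYNU was 15.2-fold higher in low glucose. Peroxisomal genes did likewise, 17 against 7 of 30 (median 0.47, camera adjusted p = 0.00452; adjusted p = 0.0604 with an estimated correlation), among them ABCD3 (4.79-fold, or 2.56-fold under normexp correction) and catalase (CAT, 2.78-fold).

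Secreted growth factors and cytokines moved the other way. Of 21 tested, 16 fell and 3 rose (median -1.96, or -0.76 under normexp correction; camera adjusted p = 0.000223; adjusted p = 0.0604 with an estimated correlation), and 6 of the 21 also belong to lists of the report. IL11 was 41.5-fold, the EGF receptor ligands AREG and HBEGF 19.1-fold and 14.4-fold, and LIF 14-fold higher in low glucose, with HBEGF at 3.38-fold and LIF at 7.13-fold under normexp correction. The 3 that rose were LIFR (1.73-fold), BMP4 (1.24-fold) and CCL20 (1.23-fold), of which LIFR is a receptor. Genes of N-glycosylation went both ways, 11 of 39 up and 19 down (median -0.13, camera adjusted p = 0.298), with TUSC3 11.9-fold higher in low glucose (3.34-fold under normexp correction) and DPM3 2.34-fold higher in high glucose.

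The share of features past the threshold, 72%, was weighed against technical explanations. Only 1 of the 35 splits into 4 and 4, the real one, gave as many as 11511 features, and the highest of the others gave 1. Every other split mixes the groups, so that their difference enters the spread and keeps the counts low. The share of 1 in 35 argues against a random grouping of these 8 samples. It cannot speak to chance differences between cultures if the replicates are technical. Position coincided with group on every slide and cannot be told apart from it by the layout. The labelled spike-in transcripts did not decide the matter. The differences of all 10 had an SD of 0.302 against 1.09 over the features, a ratio of 0.277 between the bounds of 0.25 and 0.5 set beforehand. Over the 8 spike-ins well above background on all arrays the ratio was 0.0669, with differences from -0.02 to 0.15. The other 2 were well above background on no array. The scaling is unlikely to account for the count, since the farthest value under quantile, median or spike-in scaling was 11121. A response to glucose and an effect of position both stay open, and differences in how the cultures of the groups were handled were not tested.

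LAMP3 and OSCAR, known from dendritic cells and osteoclasts, were among the largest decreases in high glucose, in a liver cell line. Monocytes or macrophages in the low glucose cultures would bring their abundant transcripts, but of 12 such transcripts only 1 (FCER1G, log2 difference -0.37 ± 0.11, SE) was well above background on all low glucose arrays and lower in high glucose. In addition, 6 of the 11 with a probe were not well above background on any low glucose array, which argues against this source. The 5 tested had 2 up and 1 down (camera adjusted p = 0.511), too few genes for this test to decide. CD14 was 7.08-fold higher in high glucose (1.81-fold under normexp correction). CORO1A was 2.05-fold higher, but its log2 difference was 0.08 under normexp correction (limma adjusted p = 0.271). Both signals in low glucose were dim (log2 -5.19 and -4.54). These rises are not counted as evidence here. A candidate explanation is activity of the MiT/TFE transcription factors, which drive lysosomal genes and, in osteoclasts, genes of bone resorption. Of 29 of their known targets, none of them in a list of the report, 20 fell and 7 rose, with a median of -0.57 (camera adjusted p = 0.0206 over the 7 lists; adjusted p = 0.0604 with an estimated correlation). FLCN (3.35-fold) and RRAGC (3.05-fold) were higher in low glucose, whereas FNIP2 was 2.51-fold higher in high glucose. Genes of osteoclast function also went both ways. PLEKHM1 (3.7-fold), OSTM1 (3.19-fold, or 1.68-fold under normexp correction) and CLCN7 (1.76-fold) were higher in low glucose. ACP5 (5.64-fold, or 2.43-fold under normexp correction), CTSK (1.22-fold) and GPNMB (1.59-fold, not past the test under normexp correction, adjusted p = 0.71) were higher in high glucose. The hypothesis stays open.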
